A study of Arabidopsis thaliana with 4 samples.

How the data were processed

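RNA from the above-ground tissue of Arabidopsis thaliana was measured on Affymetrix GeneChip arrays, 2 of wild-type plants and 2 of lwd1 lwd2 double mutants. LWD1 and LWD2 are related WD-repeat proteins that act in the circadian clock. Plants had grown for 31 days in 12 h of light and 12 h of dark, and were harvested 5 to 9 h after lights-on, per the labels. Total RNA was extracted by a method first made for pine trees, and 10 µg was converted to cDNA and labelled with biotin by in vitro transcription, per the labels' protocols.

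The deposited table holds 1 linear signal intensity for each of 22810 probe sets on each array. The software that made the values is not given in the sources used here. The trimmed mean of the deposited intensity values, with 2% of probe sets removed at each end, was 500.05 on every array, so each array had been scaled to a common mean. This scaling sets the total signal of the arrays equal and cannot show a change in total mRNA. Detection calls were not used here, so no probe set was treated as below background and no bound was given. The number of arrays limits the precision.

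The values were analysed as log2(intensity + 16). A fold change on this scale understates the change of dim genes. The arrays' median log2 values were 7.48 and 7.47 in wild type and 7.62 and 7.59 in the mutant. These medians lay within the 0.3 allowed for leaving the values as deposited. The 64 control probe sets and the 40% of probe sets with the lowest mean were left out, which left 13647 tested probe sets with a mean above a signal of about 91.5. The filter used the mean over all 4 arrays and not the genotype labels. A gene below the cutoff in wild type could pass only if it was higher in the mutant, and the reverse.

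Differences are mutant minus wild type. They were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets). The model held genotype only and had 2 residual degrees of freedom. Standard errors are limma's moderated ones. A size rule was applied beside the test: a mean difference of at least 2-fold with no overlap between the groups' arrays. Chance alone separates 2 arrays from 2 for 33.3% of probe sets. Figures were drawn with matplotlib 3.10.9.

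Gene names came from the given probe table, updated through the TAIR10.1 gene table. It gave 1 gene for 13513 probe sets, of which 13436 were matched to the gene table, and several genes for 503. Another 8730 probe sets (38.4%) are not listed in it and are unnamed here. A probe set can also read close paralogs of its gene. LWD1, LWD2 and their relative TTG1 are among the unnamed genes, so the labels could not be checked against the targeted genes. Of the clock and flowering genes to be reported whether or not they passed, GI was the only one named; CCA1, LHY, PRR9, PRR7, PRR5, TOC1, ELF4, LUX, FKF1, CO, FT, SOC1 and FLC were not analysed here.

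The samples, tests, alternatives, 25 gene lists and the rule for named genes were fixed before the data were examined. The planned lists held 326 entries, of which 42 were named on the array and 30 were tested, and none reached the 5 tested genes required for a list test. A further 43 lists were therefore written after the probe table was seen and before any difference was computed. They were tested with limma's camera with a preset correlation of 0.01, adjusted over the 35 lists with at least 5 tested genes. An estimated correlation and limma's fry were the alternative list tests. With an estimated correlation, camera rests on the 2 residual degrees of freedom, so it could hardly call any list here. The adjusted p with an estimated correlation is given below for completeness and counts neither for nor against a list. With the preset correlation, camera compares a list's genes with the other genes and is not bound by those degrees of freedom. Its p therefore does not measure the spread between plants. A gene with several probe sets was represented by the one with the highest mean. Another 17 planned lists, defined by words in gene descriptions, were not run because no descriptions were used here.

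Named genes were the 10 with the largest rise and the 10 with the largest fall among probe sets with 1 gene, an adjusted p below 0.05 and no overlap between the groups. Up to 4 members past the threshold were added from each list, or up to 2 members by size from a planned list with none. The part of the rule on lists was applied to the added lists too, for members past the threshold. Other genes given with values from a list were chosen after their values were seen.

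The procedure was tested on simulated data for the same comparison, with 13647 probe sets and 200 of them changed. It recovered 69% of the 100 changed by 1 on the log2 scale and 100% of the 100 changed by 2, with 17 calls among unchanged probe sets and none in the wrong direction. None of 34 unchanged lists was called. The noise was drawn independently for each probe set, with the variances that limma had estimated. The simulation therefore could not show how the tests, camera above all, behave where genes vary together.

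The alternatives were quantile normalization, centring on the median, no filter or a filter at the 60th percentile, offsets of 1 and 64, a variance prior without the trend or with a robust fit, the replicate number as a block, and leaving out each array in turn. When 1 array was left out, the filter was set again on the rest, so some genes were not tested, and the lone array of its group was assumed to vary like the other group.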

Results

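The series compared gene expression in wild-type Arabidopsis with that in the lwd1 lwd2 double mutant during the middle of the light period, under equal lengths of day and night. It addressed how loss of both clock proteins alters transcript levels in plants whose photoperiod response is under study. Each genotype had 2 arrays, described as biological replicates. The median signal was 162 on both wild-type arrays, and 181 and 176 on the mutant arrays. Across tested probe sets, the replicate arrays correlated at r = 0.972 in both genotypes, and arrays of different genotype at 0.932 to 0.947. The leading principal component held 63.2% of the variance and separated the genotypes. The log2 difference between the 3′ and 5′ control probe sets of actin was 1.26 and 0.91 in wild type and 1.18 and 0.99 in the mutant, which overlap. For ubiquitin it was 0.25 and −0.17 in wild type and 0.06 and 0.30 in the mutant, which overlap as well. For GAPDH it was −0.23 and −0.19 in wild type and −0.05 and 0.07 in the mutant, with no overlap and a mean difference of 0.22.

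The double mutant had much higher levels of a small set of transcripts and much lower levels of others. AT1G07050, which encodes a protein with a CCT domain, a motif shared with clock and flowering regulators, rose most among named genes. Its signal was 98.95 ± 14.1 in wild type and 2420 ± 256 in the mutant (SD, n = 2), a 21.2-fold rise. COR27, a cold- and clock-regulated gene, rose 14.8-fold (adjusted p = 1.1e-05, limma). AT1G22480, which encodes a cupredoxin, fell most among named genes with the offset of 16, with a log2 difference of −3.64 ± 0.44 (SE). Its mean mutant signal lay below that offset, and with an offset of 64 the difference was −2.48, smaller than that of AT1G62510 (−3.28). AT1G62510, which encodes a lipid-transfer-like protein, fell from a signal of 9636 to 952.

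In total, 760 of 13647 tested probe sets passed an adjusted p of 0.05, with 372 higher and 388 lower in the mutant. Of all tested probe sets, 51.5% had no overlap between the genotypes, against 33.3% by chance. All 760 calls had none, which passing the test with 2 arrays per group all but requires. The difference was at least 2-fold for 496 of them (262 higher, 234 lower) and at least 4-fold for 88 (49 higher, 39 lower). By the size rule, 335 probe sets were higher and 264 lower, against 278 and 287 after quantile normalization and 245 and 360 after centring each array on its median. This centring moved all differences by −0.13 on the log2 scale and turned the split of calls to 257 higher and 572 lower. Without the filter on dim probe sets 258 passed, and without wild-type replicate 1 the higher calls numbered 607.

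Among the calls, 350 probe sets had 1 named gene (167 higher, 183 lower), 16 had several and 394 were unnamed (192 higher, 202 lower). Unnamed probe sets were called more often than named ones, at 6.57% against 4.75% of those tested (odds ratio 1.41, Fisher's exact test, two-sided, p = 6.12e-06). Probe sets are not independent of each other in this test. The largest rises among unnamed probe sets were 4.19 and 3.80 on the log2 scale, and the largest falls had log2 differences of −3.79 and −3.48.

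The 10 largest rises among named genes ranged from 4.84-fold to 21.2-fold. Besides AT1G07050 and COR27 they included COR28 (AT4G33980), related to COR27, at a log2 difference of 3.15 ± 0.38 (SE, adjusted p = 9.7e-04). Mean wild-type signals were low for COR28 (35.0), AT4G29780 (36.0), AT2G27080 (36.1) and COR27 (63.4). They lay under the signal of about 91.5 at the filter's cutoff, so the size of these rises depends on the offset. COR28 ran from 2.26 to 3.75 over the alternatives that tested it. STZ, a zinc-finger repressor of the salt and cold response, rose by 3.68 ± 0.37 (adjusted p = 3.1e-04). EXO, a gene of cell expansion that responds to brassinosteroid, rose by 2.84 ± 0.27 (adjusted p = 2.7e-04). AT1G20030, which encodes a thaumatin-like protein, rose by 2.40 ± 0.21, AT4G27280, an EF-hand gene, by 2.28 ± 0.25, and AT2G23910 by 2.87 ± 0.37. STZ stood at 10.95 in mutant replicate 1 and 9.79 in mutant replicate 2 on the log2 scale, EXO at 11.44 and 10.65, and AT4G27280 at 11.89 and 11.07. AT4G29780 and AT2G27080 rose by 3.79 ± 0.59 and 3.14 ± 0.67, with a wide gap between the mutant arrays. AT4G29780 stood at 10.74 and 8.23, and AT2G27080 at 10.18 and 7.42. Both calls ended with a robust variance prior (adjusted p = 0.254 and 0.362) and without the filter (adjusted p = 0.0717 and 0.152), with ranges over all alternatives of 3.5e-10 to 0.254 and 1.2e-08 to 0.362.

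The 10 largest falls among named genes ranged from 4.48-fold to 12.4-fold on this scale, the upper end being AT1G22480, whose fold depends on the offset. AT1G73600, a phosphoethanolamine N-methyltransferase of phosphatidylcholine synthesis, fell from a signal of 11389 to 2248 (log2 difference −2.34 ± 0.17 (SE), adjusted p = 8.2e-05). AAH, the allantoate amidohydrolase of purine breakdown, had a difference of −2.62 ± 0.30, and AT2G27420, a cysteine protease gene, one of −2.56 ± 0.30. AT2G15020 fell 9.71-fold. The others were AT1G76960, AT5G59305, AT3G24460 and AT5G54130, with log2 differences between −2.23 and −2.16. Mean mutant signals lay under the filter's cutoff for AAH (37.0), AT5G59305 (43.8) and AT3G24460 (63.6), so the size of these falls depends on the offset too. AAH ran from −3.04 to −1.88 over the alternatives that tested it. Of the 20 genes with the largest changes, 17 stayed past the threshold in every alternative that tested them. Of the 20, 7 fell below the filter in some of the fits with 1 array left out. When a mutant array was left out, the spread came from the wild-type arrays alone. Passing such a fit says little for genes with a wide gap between the mutant arrays, such as AT4G29780 and AT2G27080. The low ends of the adjusted p ranges of these genes came from such fits. The third with a lost call, after AT4G29780 and AT2G27080, was AT3G24460 (adjusted p = 0.0995 with the robust prior and 0.127 without the filter, 1.0e-05 to 0.127 over all alternatives).

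**Figure D1:**
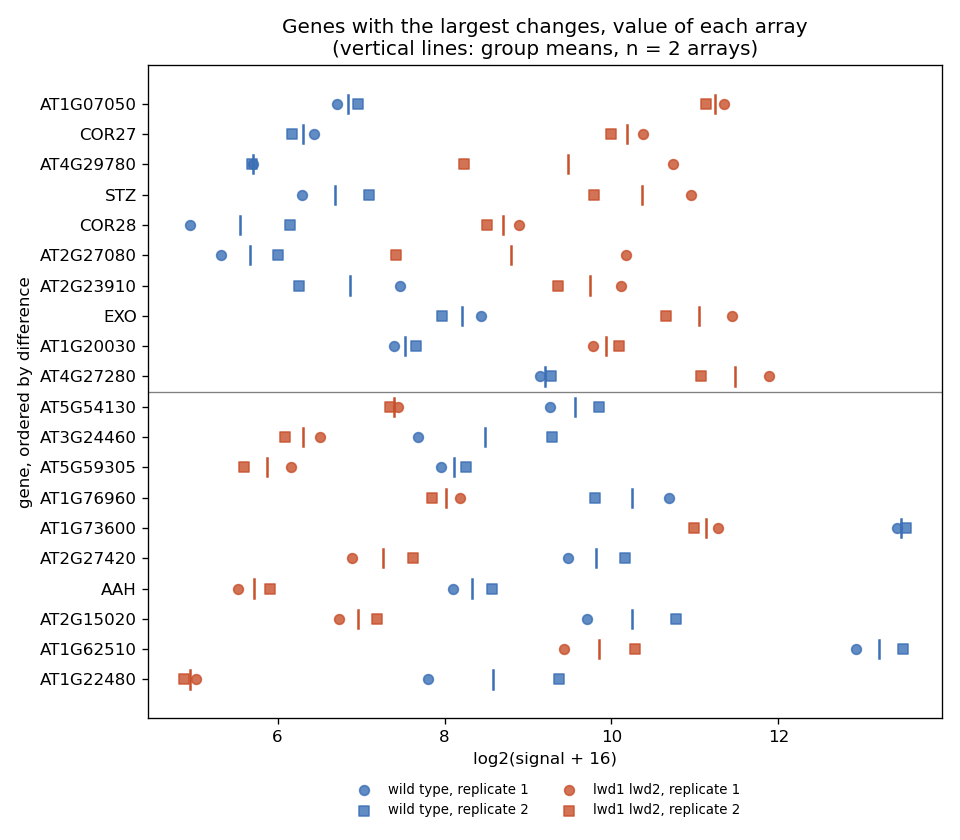
Value of each array, as log2(signal + 16) on the horizontal axis, for the 10 named genes with the largest rise and the 10 with the largest fall; circles and squares are replicates 1 and 2, blue is wild type, orange is the lwd1 lwd2 double mutant, and vertical lines are means of 2 arrays. The 20 genes were selected to have no overlap between the genotypes; AT4G29780 shows a wide gap between mutant arrays, at 10.74 and 8.23.

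Of the clock-associated genes, 3 of 10 tested rose and 1 fell. GI, which links the clock to photoperiodic flowering, rose from a signal of 740 ± 80.6 to 1620 ± 98.2 (SD, n = 2), a 2.17-fold rise (adjusted p = 0.0060). COR27 and COR28 were the others that rose. AFR, an F-box protein of phytochrome A signalling, fell 2.32-fold (adjusted p = 0.0056). TIC, XCT, RVE5, SPY, RVE6 and LIP1 did not pass, with log2 differences between −0.20 and 0.51. All samples came from 1 harvest window, 5 to 9 h after lights-on. A shift in the timing of a clock-regulated transcript therefore cannot be told apart from a change in its level. The list as a whole was not called (median 0.22, camera adjusted p = 0.146, and adjusted p = 0.798 with an estimated correlation), though it was without wild-type replicate 2 (median 0.43, adjusted p = 0.0225). The median was 0.08 without wild-type replicate 1, 0.10 without mutant replicate 2 and 0.10 after centring each array on its median. Among 6 tested genes that promote flowering GI was the one that rose, and none of 6 that repress flowering passed. CDF5, a repressor of CO, had a log2 difference of −1.01 ± 0.33 (SE, adjusted p = 0.115), and without mutant replicate 1 it was −1.40 (adjusted p = 0.0392).

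Of 8 cold-regulated genes, 4 rose: COR27, STZ, COR28 and COR15B, a protein that protects chloroplast membranes from freezing. COR15B rose 3.05-fold, from a signal of 1620 to 4972 (adjusted p = 4.1e-04). Its close relative COR15A had a log2 difference of 0.31 ± 0.19 (SE) and COR47 one of 0.51 ± 0.18, while LTI30 and XERICO stood at −0.36 and −0.33, and none of these passed. Adjusted over the list alone, 5 rose. The list was called by camera with the preset correlation (median 1.06, adjusted p = 7.8e-04). It was not called by fry (adjusted p = 0.182) or by camera with an estimated correlation (adjusted p = 0.798). Without mutant replicate 1 or 2, COR28 fell below the filter and the median of the remaining 7 was 0.54 or 0.57, the value of a gene not past the threshold in the full comparison. STZ was higher in mutant replicate 1 (10.95) than in mutant replicate 2 (9.79). COR27 and COR28 belong to the clock-associated list too.

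All 10 tested genes of mitosis and DNA replication had a positive difference, with a median of 0.63 on the log2 scale. The ones that rose were 3xHMG-box2, a chromosome-binding protein of dividing cells (2.90-fold, adjusted p = 0.0018), and the topoisomerase TOPII (2.71-fold, adjusted p = 0.0192). TOPII lost its call without the filter (adjusted p = 0.126; its alternatives ran from 0.0099 to 0.126). BUB3.1 of the spindle checkpoint stood at 0.74 ± 0.22 (SE) and the mitotic kinase AUR1 at 0.71 ± 0.22, with adjusted p = 0.0813 and 0.10. Adjusted over the list alone, 5 rose. The list was called by camera with the preset correlation (adjusted p = 4.0e-04). It was not called by fry (adjusted p = 0.182) or by camera with an estimated correlation (adjusted p = 0.798). In the same samples, 13 tested genes of anther, pollen, ovule and seed had a median of 0.31, with 10 positive, none that rose and 1 that fell. The 10 anther and pollen genes alone had a median of 0.52, with 8 positive and none past the threshold over all probe sets; adjusted over the list alone, 3 rose and 1 fell. That list was not called (camera adjusted p = 0.278), and its median was 0.20 without wild-type replicate 2. A9, the 1 tested gene of the planned anther and pollen list, varied more between replicates than between genotypes. On the log2 scale it stood at 7.42 and 5.62 in wild type and at 8.30 and 5.83 in the mutant.

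Members of the SWEET family of sugar transporters moved both ways, with 3 of 8 lower and 1 higher. SWEET13 fell 3.94-fold (adjusted p = 0.0011), from a signal of 397 to 88.1. SWEET4 had a log2 difference of −1.34 ± 0.27 (SE) and SWEET17, a fructose transporter of the vacuole, one of −0.84 ± 0.18. SAG29, a senescence gene also known as SWEET15 and not in that list, fell from a signal of 275 to 54.6 (adjusted p = 0.0022). SWEET1 rose by 0.85 ± 0.21. The list was not called (median −0.39, camera adjusted p = 0.146, and adjusted p = 0.798 with an estimated correlation), though it was without wild-type replicate 1 (median −0.80, 7 genes, adjusted p = 0.0292) or 2 (median −0.60, adjusted p = 0.0472). With no filter, 14 members were tested and the median was 0.18 (adjusted p = 0.648).

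**Figure D2:**
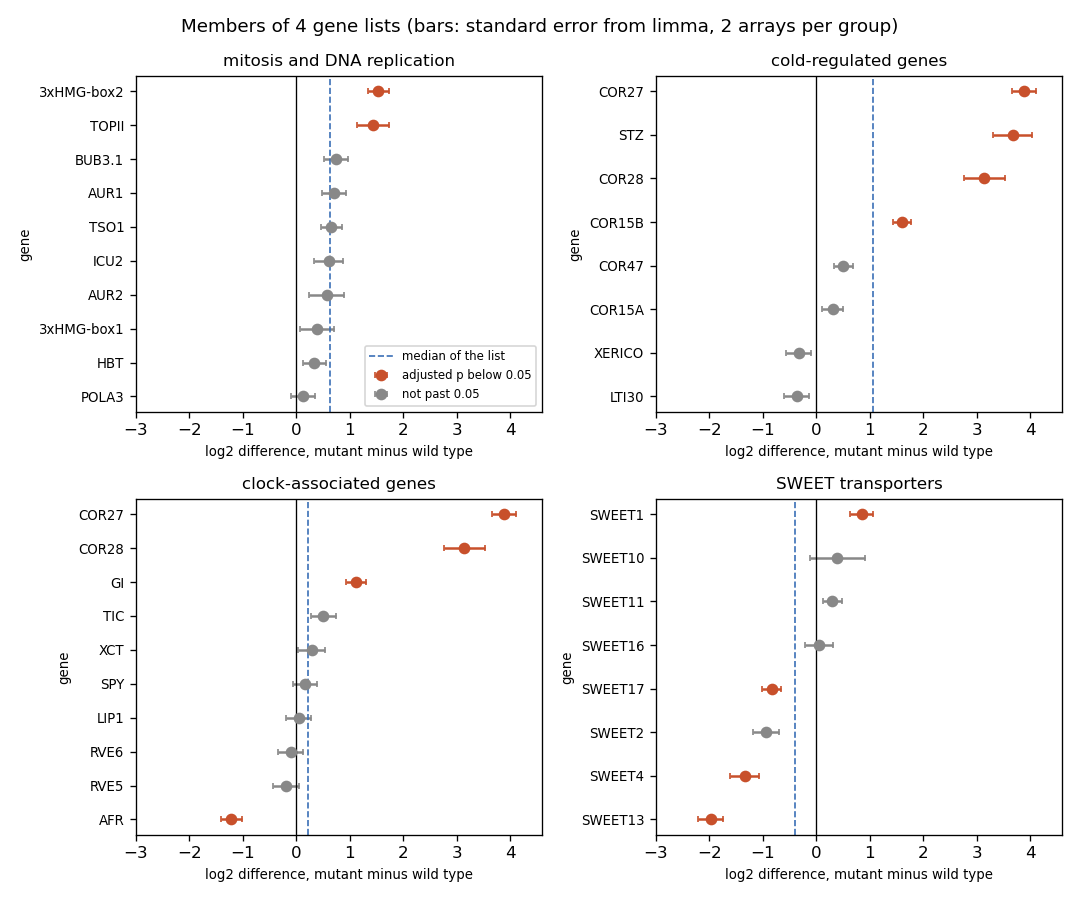
Log2 difference, mutant minus wild type, on the horizontal axis for each tested member of 4 gene lists; points are limma estimates from 2 arrays per genotype, bars are 1 standard error, orange points passed an adjusted p of 0.05 and dashed lines are list medians. All 10 genes of mitosis and DNA replication lie above 0 (median 0.63), while 4 of the 8 cold-regulated genes carry most of that list's shift (median 1.06).

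Nuclear genes of photosynthesis and chlorophyll synthesis showed small differences. Of 29 tested, PORB, a protochlorophyllide reductase, rose 1.61-fold, and NdhS, a subunit of the chloroplast NDH complex, fell 1.78-fold. The median was −0.20 (camera adjusted p = 0.0988, and adjusted p = 0.798 with an estimated correlation). It was −0.07 after quantile normalization and −0.10 without mutant replicate 1. In the other direction, it was −0.32 after centring each array on its median and −0.28 without mutant replicate 2. None of 67 tested plastid-encoded genes passed, and their median was −0.14 (camera adjusted p = 0.146, and adjusted p = 0.798 with an estimated correlation). The plastid-encoded median was −0.18 without wild-type replicate 1 and without mutant replicate 1. It was −0.04 without wild-type replicate 2 and without mutant replicate 2. After quantile normalization it was −0.07, and after centring each array on its median −0.27. Genes often used as controls of constant level had log2 differences of 0.01 ± 0.19 for TIP41, 0.06 ± 0.20 for SAND and −0.03 ± 0.18 for UBC21 (SE), none past the threshold.

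A few members of several other gene families changed. Where a family had at least 5 tested genes, camera did not call it (adjusted p from 0.0988 to 0.921). The defensin genes LCR69 and LCR68 rose 3.41-fold and 2.24-fold from high wild-type signals of 2798 and 3155, and the third tested defensin did not pass. LCR68 lost its call without the filter (adjusted p = 0.0798; 2.9e-04 to 0.0798 over all alternatives). The expansin-like gene EXLA1 rose 4.21-fold, as 1 of 11 tested expansins. Its log2 difference of 2.07 was 1.25 without mutant replicate 1 and 2.89 without mutant replicate 2, as the mutant arrays stood at 10.79 and 9.15. Its call ended with the robust prior (adjusted p = 0.267) and without the filter (adjusted p = 0.131; 1.4e-07 to 0.267 over all alternatives). XTH16, 1 of 4 tested xyloglucan endotransglucosylases, rose 2.48-fold, a log2 difference of 1.31 that was 0.74 without wild-type replicate 2. GH9B5, 1 of 6 endoglucanases, fell 2.24-fold, and TBL36, 1 of 14 wall acetylation proteins, fell 2.22-fold. SCPL49, 1 of 14 serine carboxypeptidase-like genes, rose 2.22-fold, and BGLU44, 1 of 7 beta-glucosidase genes, 1.88-fold. BETA-VPE, a vacuolar processing enzyme of seeds, fell 2.21-fold, and CYP71B24, 1 of 10 tested cytochromes P450 of its subfamily, fell 2.53-fold. ORA47, a transcription factor of the jasmonate response, rose 2.16-fold, as 1 of 8 tested jasmonate genes.

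Of the planned lists pooled, 30 genes were tested; GI and COR15B rose and SAG29 fell, and the same numbers passed adjusted over the lists alone. Of the 48 named genes past the threshold, 16 lost it when 1 array was left out, at adjusted p between 0.0530 and 0.198. These were SWEET1, SWEET4, SWEET17, PORB, NdhS, ORA47, XTH16, GH9B5, TBL36, BETA-VPE, CYP71B24, BZIP61, TET8, RALFL33, UGT71B1 and UBC30. Among the 33 lists not called, the camera adjusted p ran from 0.0988 to 0.921.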

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

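No alternative reversed the direction of a called named gene, and 26 of the 48 called named genes passed in all alternatives that tested them. That no direction reversed was all but fixed in advance. Every called gene had no overlap between the genotypes, so leaving out 1 array could not reverse it. Scaling moved the median difference by −0.07 or −0.13, less than the smallest called named difference (PORB, 0.68). Without the filter, 22745 probe sets were tested and 258 passed (114 higher, 144 lower), while 1235 met the size rule (765 higher, 470 lower). The cause of the fall in calls was not tested. A filter at the 60th percentile left 378 by the size rule (197 higher) and 1 gene list, since fewer probe sets were tested. The cell division list then had too few genes to test. With 1 array left out, the size rule is looser than in the full comparison, since 1 array avoids overlap with 2 more easily by chance. Leaving out 1 array gave 561 to 1095 calls (290 to 607 higher, 271 to 488 lower) and 593 to 870 by the size rule (335 to 551 higher); the highest counts came without wild-type replicate 1, and the cause was not tested. Gene lists past the threshold numbered 2 to 4 when 1 array was left out, and 0 with an estimated correlation or with fry. With an estimated correlation, most lists shared an adjusted p of 0.798, so this value does not tell lists apart. The estimate itself was 0.06 for the cell division list and −0.08 for the cold-regulated list, against the preset 0.01. For both the cell division and the cold-regulated list, the adjusted p was 0.798 with an estimated correlation and 0.182 with fry, which asks a different question. It stayed below 0.05 in the other alternatives that tested them, and was 0.0150 for the cold-regulated list without STZ, an alternative chosen after seeing the data. The differences of replicate 1 minus 2 correlated at 0.09 between the genotypes, so the numbers were not read as pairs. With the replicate block, 676 probe sets passed (324 higher, 352 lower). Other counts stayed within 1.5 times of those reported, from 553 without the intensity trend to 844 with a robust prior. The other 2 ways of splitting the 4 arrays, also added later, called 0 probe sets each with limma. At an unadjusted p under 0.05 they gave 200 and 87 probe sets, against 2716 for genotype. Each of them puts 1 wild-type and 1 mutant array in each group, so the genotype difference enters the residual spread. Few calls were therefore to be had whatever the error rate, and these splits are no null for the genotype calls. The 3 splits are also too few for a share under 0.05. Dim probe sets limit what the arrays can show.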

Other observations

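The test of flower tissue below was chosen only after the cell division result was seen. Genes that respond within minutes to touch or wounding were listed after the values of 5 of them had been seen, and the rest were then examined. The 5 were STZ, EXO, AT4G27280, AT4G29780 and AT2G27080, which are 5 of the 10 largest named rises. All 5 were higher in mutant replicate 1 than in replicate 2, and STZ is also 1 of the 4 cold-regulated genes that rose. The list of rapid response genes held 62 genes, of which 38 were named on the array and 23 were tested. Members below the filter's cutoff in wild type were tested only if they were higher in the mutant, which favours positive differences. Of the 23, 9 rose in the double mutant and none fell, and 19 had a positive difference. Among the 18 whose values had not been seen, 4 rose and the median log2 difference was 0.85. AT1G32920 rose by 1.96, AT1G76600 by 1.80, AT1G19380 by 1.76 and ORA47 by 1.11, while the calmodulin-like genes CML23, CML42 and CML41 stood at 1.03, 0.37 and 0.24 without passing. These genes were picked from the list after their values were seen.

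For the rapid response genes, the median of the 18 was 0.76 after quantile normalization, against 0.85 as deposited. This normalization moved the median of all probe sets by only −0.07, so a large drop was hardly possible. The values show that the rise of these genes is larger than this shift in scaling, and no more. Whether the response of the whole list sat in 1 mutant sample stays open. In mutant replicate 2 the median above the wild-type mean was 0.38, with a bootstrap interval over genes from −0.12 to 0.57 (95%). The interval covers the spread among genes on that array, not the spread between plants. In mutant replicate 1 the median was 1.35, and 17 of the 18 were higher in replicate 1. The 9 that rose stood above the wild-type mean in replicate 2 too, by at least 1.75 for the 5 seen first and by 0.89 to 1.29 for the other 4, though passing the test favours such genes. Handling at harvest may contribute to these rises and, with 2 arrays per group, cannot be told apart from an effect of the mutation, which stays open and was not tested separately.

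For the genes of mitosis and DNA replication, the median was 0.54 after quantile normalization, against 0.63 as deposited. A large drop was hardly possible here either, so this too shows only a rise larger than the shift in scaling. A larger share of flower tissue in the mutant samples may contribute. The median of 13 flower genes, 0.31, lay at the 97.25th percentile of 10000 random lists matched on mean signal, just under the level set for counting the test in its favour. Over 20 repeated draws of such lists the percentile ran from 96.8 to 97.6, on both sides of that level, so the test decides nothing. A direct effect of genotype on dividing tissue stays open as well, untested.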
